A study of Macaca fascicularis with 64 samples.

How the data were processed

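Bulk RNA sequencing was carried out on tissues of cynomolgus monkeys (Macaca fascicularis), with 56 libraries of newborn tissue and 8 libraries of fetal tissue. Per the labels' protocols, tissue was ground in liquid nitrogen, total RNA was taken with TRIzol and cleaned on RNeasy columns, libraries were made with the TruSeq RNA kit, and sequencing was on an Illumina HiSeq instrument. The submitters' processing notes name CASAVA, HISAT 0.1.6 and Cufflinks 2.0.2, with no role or order. The genome build, the annotation and any strand setting are not given in the sources used here, so no coordinates are printed, and overlapping or antisense genes cannot be separated.

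The authors deposited their values as FPKM, fragments scaled by gene length and by mapped fragments, in a table of newborn libraries and a separate table of fetal libraries, each with 28141 genes. FPKM is not a count and keeps no read depth, so the depth of each library is unknown and no counting interval or lower limit of detection is given. Genes are named as in the tables, and 721 of the 11294 genes listed under a LOC identifier were given the current symbol for that identifier from a RefSeq gene table of the species, used for names alone. A further 10573 kept the identifier. Of the genes, 1536 were listed at 0 in all 64 libraries. A value of 0 can be a failed estimate and is given as listed at 0.

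The titles name KO2, KO3, WT2 and WT3 in each of the 7 newborn tissues, and these were read as 4 animals, with the last number in the title read as a repeat library of that animal. Whether repeats are separate pieces of tissue is not stated. The log2(FPKM + 1) values of the 2 repeat libraries were averaged, which left 2 KO against 2 WT animals in each tissue. The fetal libraries are wild type, from gestation month 2 or month 4, of brain or muscle, with 2 libraries per month and tissue. Nothing states that these came from separate fetuses, so the fetal p-values measure only the spread between libraries, which may be technical.

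Each comparison was fitted by itself with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend on expression), on genes with a mean FPKM of 1 or more over the libraries of the comparison. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the genes tested. A log2 change is on the log2(FPKM + 1) scale and understates the change of low genes. The standard error (SE) is limma's moderated one. KO was compared with WT in each newborn tissue and after averaging each animal over the 7 tissues. The KO change in a tissue was compared with the mean KO change in the other 6 tissues from each animal's own difference, so that the test is of the difference itself. Month 4 was compared with month 2 in fetal brain and in fetal muscle, within the fetal table. An exact two-sided permutation test of 2 against 2 animals cannot go below p = 0.33.

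Gene lists of pathways and cell types, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists with 5 or more tested members were tested with camera from limma with an inter-gene correlation of 0.01, which compares the list with all other genes, and adjusted over the lists of a comparison, and the adjusted p of a list is camera's unless stated. Estimating the correlation from the data and fry, which asks whether a list moves on balance but not against other genes, were the alternatives. No list stayed past the threshold with an estimated correlation in any comparison, while fry called 4 of the 102 list calls of the newborn tissues. Members past the threshold were counted over all genes tested and adjusted over the list alone. Fetal stage genes were those with an adjusted p under 0.05 and a log2 change of 1 or more in size between the months, up to 500 per direction.

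Named genes were SIRT6 first, then the 10 highest and 10 lowest log2 changes past the threshold in brain and muscle, 5 and 5 in the other tissues, and 8 and 8 in the fetal comparisons. A named gene had a symbol, a mean of 5 FPKM or more in the higher group, and all KO libraries on one side of all WT libraries. Where none passed in a direction, the 3 with the smallest p are given as values that did not pass. IGF2 was named in each tissue, as were up to 8 genes called the same way in the most tissues and up to 4 members with the smallest p of each list described. Lists had members described when they were specific to the tissue or had at least 2 members past the threshold, a choice made after the list results were seen. H19, XIST, Y-linked genes and mitochondrially encoded genes were not analysed here.

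Alternatives were a pseudocount of 0.1, no level filter, a filter at 5 FPKM, quantile normalisation within the tissue, libraries as replicates, libraries with the animal as a correlated unit (duplicateCorrelation with statmod 1.5.0), 1 fit of all tissues, the animal number as a block, and leaving out each animal or library in turn. The animal numbers do not pair animals across genotypes by any label, so the fits without a block were the reported ones. Reads of near-identical genes (myosin heavy chains, globins, CYP2C enzymes) and of overlapping genes may have been split between them by the authors' counting, and values of these genes are uncertain.

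The procedure was tested on simulated data with 50 genes changed at each of 2-, 4-, 8- and 16-fold. All 16-fold changes were recovered, and all 8-fold ones except in lung (92%). Recovery of 4-fold changes was 34% (lung) to 100% (kidney) in newborn tissues, 98% in fetal brain and 100% in fetal muscle. For 2-fold changes it was 2% (thymus and lung) to 42% (kidney), 72% and 92%. False calls made up 2.76% of calls in brain and 6.56% (lung) to 13.1% (liver) elsewhere, above the 5% the threshold stands for. In the data CKM in brain (13.1-fold) and PIGY in lung (29.4-fold) were not called, so these rates need not hold there.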

Results

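Gene expression was measured by RNA sequencing in cynomolgus monkeys labelled as SIRT6 knockout or wild type. SIRT6 encodes a nuclear deacetylase of the sirtuin family that acts on histones. The series title names developmental retardation with SIRT6 deficiency. The newborn set held 56 libraries from 2 knockout animals (KO2 and KO3) and 2 wild-type animals (WT2 and WT3), with 2 libraries each of brain, muscle, thymus, liver, heart, lung and kidney. The fetal set held 8 wild-type libraries of brain and muscle, with 2 libraries from gestation month 2 and 2 from month 4 in each tissue. Levels are FPKM per animal, as the mean of its 2 libraries, in the order KO2, KO3, WT2, WT3, and each newborn test had n = 2 KO and 2 WT animals. Log2 changes are limma estimates with their standard error (SE). In simulated data 2.76% (brain) to 13.1% (liver) of the calls were false at the adjusted p threshold of 0.05, so more calls can be false than it implies.

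SIRT6 itself was given first, as the targeted gene. In brain its transcript stood at 9.54 and 11.5 FPKM in KO and 12.4 and 12.1 in WT. In muscle it stood at 4.99 and 8.81 against 8.13 and 8.36. In thymus it was at 4.29 and 8.94 against 8.86 and 10.4, and in liver at 3.07 and 6.87 against 6.18 and 8.62. In heart it stood at 8.53 and 12.4 against 6.41 and 8.29. In lung it was at 7.64 and 11.8 against 8.05 and 8.16, and in kidney at 5.24 and 11.8 against 11 and 11.5. SIRT6 passed the test in none of the 7 tissues, with limma adjusted p values from 0.54 in kidney to 0.94 in lung. KO2 had the lowest level of the 4 animals in each tissue except heart, while KO3 lay within or above the 2 WT values in each tissue except brain. The kind of mutation is not given in the sources used here, and a gene-level FPKM misses a small deletion or frameshift, so these values do not check the genotype labels.

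KO and WT newborns were compared after each animal was averaged over its 7 tissues. HBZ, the zeta globin of embryonic red cells, was higher in KO, and HBB, the beta globin of adult red cells, was lower. The median log2 change of all genes in this average was −0.11, and changes in this paragraph are relative to it. The adjusted p tests the change before this subtraction, here and wherever changes are given relative to such a median. HBZ rose by 3.92 (SE 0.3, limma adjusted p = 9.1e-05) and HBB fell by 2.91 (SE 0.21, adjusted p = 4.8e-05). IGF2, a fetal growth factor expressed from the paternal allele, rose by 1.61 (SE 0.22, adjusted p = 0.012). KLF9, a transcription factor induced by glucocorticoids, fell by 2.09 (SE 0.33, adjusted p = 0.014), and PDK4, the fasting-induced kinase that limits pyruvate oxidation, fell by 1.98 (SE 0.32, adjusted p = 0.015). Complement C1QB, C1QC and C1QA, made mainly by macrophages, fell, at −2.01, −2.02 and −1.96, with adjusted p values of 0.015, 0.019 and 0.02. P4HA1, a collagen prolyl hydroxylase induced by hypoxia, rose by 2.01 (adjusted p = 0.02), and the angiogenic factor VEGFA rose by 1.51 (adjusted p = 0.039).

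In this average 74 of 15038 genes passed the threshold, 38 higher and 36 lower in KO. Among 22 glucocorticoid and fasting response genes, 4 fell and 0 rose, or 11 and 0 adjusted over the list alone, and the list had a median log2 change of −0.76 (adjusted p = 1.2e-11, adjusted p = 0.61 with an estimated correlation). Among 20 macrophage and monocyte genes, 3 fell and 0 rose, or 10 and 0 adjusted over the list alone, with a median of −0.77 (adjusted p = 2.1e-10, adjusted p = 0.75 with an estimated correlation). Of 21 erythroid genes, 2 rose, HBZ and the alpha globin chaperone AHSP, and 1, HBB, fell, or 8 and 1 adjusted over the list alone, with a median of 0.55 (adjusted p = 6.3e-10, adjusted p = 0.75 with an estimated correlation). Of 27 hypoxia genes, 2 rose and 0 fell, or 6 and 0 adjusted over the list alone, with a median of 0.21 (adjusted p = 4e-04, adjusted p = 0.75 with an estimated correlation). By tissue their medians ran from −0.52 (lung) to 0.16 (liver) in KO2 and 0.39 (brain) to 1.4 (lung) in KO3. KO3 carried it. Of 49 ribosomal protein genes, 0 passed over all genes and 21 rose adjusted over the list alone, with a median of 0.46 (adjusted p = 9e-27, adjusted p = 0.59 with an estimated correlation). Camera called 13 of 25 lists here, against 0 with an estimated correlation and 0 by fry. After quantile normalisation limma called 7 genes, all of them among the 74 and 71.4% of them higher against 51.4% before, and HBZ (adjusted p = 0.018) and HBB (adjusted p = 0.022) were among those that passed. Leaving out KO2 gave 49 genes, KO3 1100, WT2 96 and WT3 119, and without KO2 the heat shock list turned to a mean of −0.12. PDK4, P4HA1, C1QB, C1QC, C1QA, VEGFA and AHSP missed the threshold without KO2, VEGFA and AHSP without WT2 or WT3, and the hypoxia list without KO3.

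Tissue by tissue, HBZ was called higher in 4 tissues and stood higher in KO in all 7. Its FPKM was 300 and 546 against 7.34 and 2.51 in liver, 80.9 and 34.6 against 1.67 and 4.73 in heart, 10.3 and 22 against 0.354 and 0 in muscle, and 16.3 and 5.32 against 1.73 and 1.42 in kidney. HBB was called lower in the same 4 tissues and its KO mean stood lower in all 7. In lung its level in KO3 was 2890 FPKM against 2670 and 2960 in WT, with 291 in KO2. IGF2 was called higher in muscle, at 2760 and 2120 FPKM against 831 and 763 (log2 change 1.60, SE 0.33, adjusted p = 0.0077), and in kidney, at 1010 and 1260 against 404 and 369 (1.54, SE 0.32, adjusted p = 0.026). In the other 5 tissues IGF2 did not pass, with log2 changes relative to all genes from 0.65 (adjusted p = 0.7) in heart to 2.43 (adjusted p = 0.39) in brain. KLF9, PDK4, the interferon-induced IFI27 and the aspartate aminotransferase GOT1 were each called lower in 3 tissues, and the acute phase protein CRP and the secreted glycoprotein AZGP1 in 2, the liver and the kidney. Muscle and kidney shared 43 genes called lower, against 11 for independent lists, and 18 called higher, against 1.1. Liver and kidney shared 35 called lower, against 5.9. IGF2 missed the threshold in muscle without KO2 or KO3 and in kidney without WT2 or WT3. HBZ missed it in kidney without KO2, WT2 or WT3 and in liver and heart without KO2, and KLF9 in muscle without KO2. IFI27 missed it in muscle without KO2 (0.35), KO3 (0.25) or WT3 (1) and in kidney without KO2 (0.051) or WT3 (0.1). GOT1 missed it in muscle without KO2 (0.22) or WT3 (0.58) and in kidney without WT2 (0.064) or WT3 (0.16). In kidney CRP missed it without WT2 (0.17) or WT3 (0.13) and AZGP1 without WT2 (0.16). The tissues come from the same 4 animals, so part of the excess may come from shared animals. With no level filter limma called 0 genes in each of the 7 tissues, with 1130 in thymus to 3656 in kidney at an unadjusted p under 0.05.

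**Figure D1:**
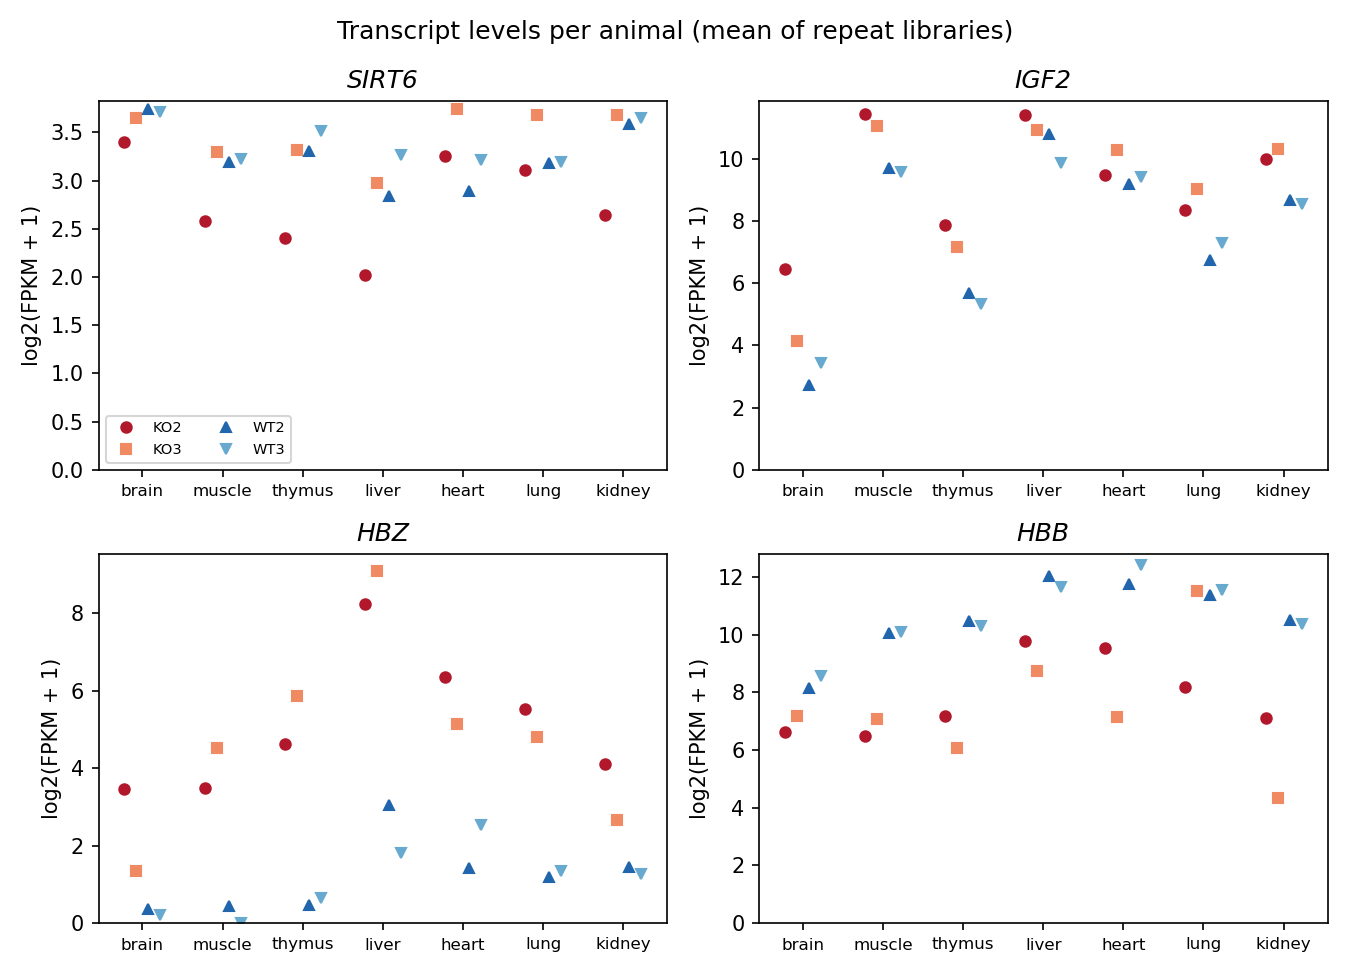
Levels of SIRT6, IGF2, HBZ and HBB as log2(FPKM + 1) on the vertical axis in 7 newborn tissues, with 1 point per animal (the mean of its 2 libraries; KO2 and KO3 in red and orange, WT2 and WT3 in blue). HBZ lies above both WT animals in both KO animals in all 7 tissues, as in liver at 300 and 546 FPKM against 7.34 and 2.51.

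Muscle was compared between the genotypes. Myosin heavy chains of early muscle were higher in KO and those of mature fast fibres were lower. MYH3, the embryonic myosin heavy chain, stood at 468 and 306 FPKM in KO against 14.3 and 4.16 in WT and rose by 5.42 log2 units (SE 0.5, limma adjusted p = 1.7e-07). MYH8, the perinatal chain, rose by 2.72 (SE 0.54, adjusted p = 0.0067), and CHRNG, the fetal subunit of the acetylcholine receptor, rose by 2.72 (SE 0.5, adjusted p = 0.0037). MYH1 and MYH4, chains of adult fast fibres, fell, at −4.49 (SE 0.43, adjusted p = 3.1e-07) and −3.72 (SE 0.82, adjusted p = 0.012). PEG10 and RTL1, imprinted genes derived from retrotransposons, rose by 3.76 (SE 0.47, adjusted p = 4e-05) and 3.48 (SE 0.47, adjusted p = 9.8e-05).

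UCP3, PDK4 and TRIM63 were lower in KO muscle, and G0S2 and PPP1R3C were higher. UCP3, a mitochondrial carrier induced by fasting, stood at 0.304 and 0.532 FPKM against 75 and 153 and fell by 6.26 (SE 0.5, limma adjusted p = 1.8e-08). PDK4 fell by 5.66 (SE 0.59, adjusted p = 1.5e-06), TRIM63, a ubiquitin ligase of muscle atrophy, fell by 4.03 (SE 0.58, adjusted p = 0.00022), and FKBP5, a chaperone induced by glucocorticoids, fell by 4.01 (SE 0.61, adjusted p = 0.00044). CHAC1, a glutathione-degrading enzyme of the stress response, fell (−6.08, adjusted p = 7.3e-08), as did the glutamine synthetase GLUL (−3.84, adjusted p = 4e-05), the glycolytic regulator PFKFB3 (−3.83, adjusted p = 4.2e-05) and the receptor GPR157 (−3.58, adjusted p = 0.0045). G0S2, an inhibitor of triglyceride lipase, LRTM1, a membrane protein of muscle, PPP1R3C, a glycogen-targeting subunit, and CPLX1, a regulator of vesicle fusion, rose by 3.24, 3.12, 2.99 and 2.73, with adjusted p values of 0.00051, 0.00084, 0.012 and 0.012. HBZ rose by 3.8 and HBB fell by 3.29, with adjusted p values of 5.8e-05 and 1.2e-05.

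By fixed list, 6 of 22 fetal and regenerating muscle genes rose and 0 fell in KO, or 9 and 1 adjusted over the list alone (median log2 change 0.99, adjusted p = 1.1e-10, adjusted p = 0.32 with an estimated correlation). Of 32 fast-twitch and sarcomere genes, 9 fell and 0 rose, or 14 and 1 adjusted over the list alone (median −0.71, adjusted p = 2.5e-11, adjusted p = 0.32 with an estimated correlation). They included ACTN3, the alpha-actinin of fast fibres, at −1.91. Of 15 slow-twitch genes, 6 fell and 0 rose, or 8 and 1 adjusted over the list alone (median −1.26, adjusted p = 1.8e-06, adjusted p = 0.61 with an estimated correlation). Myoglobin, MB, was at −1.93 and the troponin TNNC1 at −2.25. Of 19 glucocorticoid and fasting genes, 9 fell and 0 rose, or 16 and 0 adjusted over the list alone (median −1.86, adjusted p = 2e-19, adjusted p = 0.61 with an estimated correlation). Their median was −3.05 in KO2 and −0.75 in KO3. Of 16 imprinted genes, 4 rose and 0 fell, or 8 and 0 adjusted over the list alone (median 1.18, adjusted p = 7.1e-11, adjusted p = 0.32 with an estimated correlation). Those that rose were PEG10, RTL1, IGF2 and the Notch ligand relative DLK1. Of 42 nuclear-encoded oxidative phosphorylation genes, 2 fell and 0 rose, or 19 and 0 adjusted over the list alone (median −0.99, adjusted p = 2.7e-17, adjusted p = 0.61 with an estimated correlation). Among markers of blood-derived cells, 3 of 15 macrophage genes and 4 of 11 neutrophil genes fell, or 5 and 11 adjusted over the list alone, at medians of −1.01 and −1.63 (camera adjusted p = 3e-07 and 6.7e-12, adjusted p = 0.76 and 0.61 with an estimated correlation). The macrophage median was −2.03 in KO2 but −0.17 in KO3, the neutrophil one −1.7 and −1.55, with WT2 and WT3 at −0.8 and 0.8 about the WT mean, and the slow-twitch one −0.70 and −1.90. Of 14 adipocyte genes, 0 passed over all genes and 3 were lower adjusted over the list alone (median −0.84, −2.2 in KO2 and 0.27 in KO3, adjusted p = 0.0012, adjusted p = 0.76 with an estimated correlation), and without KO2 their mean turned to 0.42. Of 23 fibroblast genes, 0 passed, also adjusted over the list alone (median −0.56, adjusted p = 0.0082, adjusted p = 0.76 with an estimated correlation), and the list missed the threshold without KO3 (0.95) or WT2 (0.85), as the adipocyte list did without WT2 (0.24). Among 20 heat shock and unfolded protein genes, CHAC1 and the co-chaperone DNAJB9 fell (adjusted p = 7.3e-08 and 0.033), while the chaperone HSP90AA1 stood at 2420 FPKM in KO2 and 77.8 in KO3 against 66.6 and 57.5 (adjusted p = 0.073), and adjusted over the list alone 8 rose and 3 fell (median 0.78, adjusted p = 0.04, adjusted p = 0.76 with an estimated correlation).

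In muscle 281 of 12087 genes passed, 90 higher and 191 lower. After quantile normalisation 14 of the 281 still passed, with MYH3 (adjusted p = 0.024), MYH1 (0.023), UCP3 (0.0099), CHAC1 (0.02), PEG10 (0.02), RTL1 (0.02), HBZ (0.023) and HBB (0.024) among them and the other named genes not. Leaving out KO2 gave 97 genes, WT2 159, WT3 136 and KO3 279, and without KO2 the heat shock list turned to a mean of −0.27. Without KO2 MYH4 (adjusted p = 0.45), G0S2 (0.1), PPP1R3C (0.075), GPR157 (0.081), ACTN3 (0.13), DLK1 (0.19) and DNAJB9 (0.16) missed the threshold. The same held without KO3 for MYH8 (0.12), MYH4 (0.057), CHRNG (0.055), PPP1R3C (0.27), CPLX1 (0.058), MB (0.16), TNNC1 (0.17), DLK1 (0.067) and the slow-twitch list (0.47), without WT2 for LRTM1 (0.056) and DNAJB9 (0.35), and without WT3 for MYH4 (0.34), CHRNG (0.17), PPP1R3C (0.15), DLK1 (0.24) and DNAJB9 (0.51).

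Kidney was asked the same question. Transporters and enzymes of the mature tubule were lower in KO, and genes of podocytes, the filtering cells, were higher. MIOX, an inositol oxygenase of the proximal tubule, stood at 38.1 and 28.4 FPKM against 885 and 699 and fell by 4.54 log2 units (SE 0.3, limma adjusted p = 0.0012). CYP27B1, the enzyme that activates vitamin D, fell by 4.63 (SE 0.34, adjusted p = 0.0012), the heme oxygenase HMOX1 fell by 5.23 (SE 0.44, adjusted p = 0.0012), and the glucose-6-phosphatase G6PC fell by 4.41 (SE 0.56, adjusted p = 0.0049). UMOD, uromodulin of the loop of Henle, stood at 118 and 272 FPKM against 2720 and 2440 and fell by 3.84 (SE 0.42, adjusted p = 0.0027). SHISA3, a secretory-pathway inhibitor of Wnt and FGF signals, rose by 3.28 (SE 0.38, adjusted p = 0.0033), and LYPD1, COL2A1 (a cartilage collagen), SAMD11 and B4GALNT4 rose by 3.47, 2.85, 2.81 and 2.59, with adjusted p values of 0.013, 0.008, 0.0084 and 0.0068.

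Of 30 proximal tubule genes, 22 fell and 0 rose in KO kidney, or 29 and 0 adjusted over the list alone (median −1.80, adjusted p = 2.1e-21, adjusted p = 0.22 with an estimated correlation). Fry called the proximal tubule, collecting duct and podocyte lists as well (adjusted p = 0.038 each). They included the carboxylate transporter SLC13A3 at −3.15, the water channel AQP1 at −2.16 and the phosphate transporter SLC34A1 at −2.20. Of 18 genes of the loop of Henle and distal tubule, 8 fell and 0 rose, or 15 and 0 adjusted over the list alone (median −1.52, adjusted p = 8.7e-11, adjusted p = 0.78 with an estimated correlation). EGF was at −3.39 and the thiazide-sensitive cotransporter SLC12A3 at −2.54. Of 19 collecting duct genes, 6 fell and 0 rose, or 15 and 0 adjusted over the list alone (median −1.34, adjusted p = 1e-08, adjusted p = 0.3 with an estimated correlation). The vasopressin-regulated water channel AQP2 was at −2.45. Of 15 podocyte genes, 3 rose and 0 fell, or 6 and 0 adjusted over the list alone (median 0.67, adjusted p = 1.9e-06, adjusted p = 0.3 with an estimated correlation). They included the transcription factor FOXC2 at 1.32 and the filament protein NES at 1.18. Of 16 nephron progenitor genes, 1, the Wnt effector LEF1, rose by 1.61 and 0 fell, also adjusted over the list alone (median 0.59, adjusted p = 0.0052, adjusted p = 0.8 with an estimated correlation). Of 42 oxidative phosphorylation genes, 18 fell and 0 rose, or 39 and 0 adjusted over the list alone (median −1.11, adjusted p = 9.8e-18, adjusted p = 0.78 with an estimated correlation). Of 21 glucocorticoid and fasting genes, 8 fell and 0 rose, or 12 and 0 adjusted over the list alone (median −1.23, adjusted p = 8.7e-09, adjusted p = 0.52 with an estimated correlation). KLF9 was at −2.46 and the kinase SGK1 at −2.46. Among 17 imprinted genes, IGF2, ASCL2 and MEST rose and DLK1 fell by 1.33 (adjusted p = 0.046), or 6 and 1 adjusted over the list alone (median 0.58, adjusted p = 0.0061, adjusted p = 0.8 with an estimated correlation). Medians in KO2 and KO3 were 0.35 and 0.93 for nephron progenitor genes and 0.25 and 1 for imprinted genes. Fibroblast genes stood higher beside the podocyte genes, with 0 of 24 past the threshold over all genes and 9 higher adjusted over the list alone (median 0.78, adjusted p = 3e-04, adjusted p = 0.78 with an estimated correlation). Of 15 macrophage genes, 1 fell and 0 rose, or 3 and 0 adjusted over the list alone (median −0.61, −1.58 in KO2 and −0.22 in KO3, adjusted p = 0.018, adjusted p = 0.84 with an estimated correlation), and the list missed the threshold without KO2 (adjusted p = 0.52).

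In kidney 806 of 13937 genes passed, 142 higher and 664 lower. After quantile normalisation 785 passed, 637 of them among the 806, and the share higher went from 17.6% to 31.5%, while HBZ no longer passed (adjusted p = 0.067). Leaving out KO2 gave 710 genes, KO3 1508, WT2 198 and WT3 172, and no animal's removal ended MIOX, CYP27B1, HMOX1, G6PC, UMOD, SHISA3 or B4GALNT4. Without WT3 LYPD1 (adjusted p = 0.068), COL2A1 (0.055), SAMD11 (0.054), AQP1 (0.06), SLC34A1 (0.058), AQP2 (0.06), FOXC2 (0.16), NES (0.27), LEF1 (0.16), ASCL2 (0.08), MEST (0.22) and DLK1 (0.4) missed the threshold. Without WT2 AQP1 (0.06), SGK1 (0.066), FOXC2 (0.25), NES (0.23), LEF1 (0.18), ASCL2 (0.26), MEST (0.28) and DLK1 (0.28) did, without KO2 HBZ (0.081), FOXC2 (0.1), NES (0.12), LEF1 (0.1) and ASCL2 (0.067), and without KO3 the nephron progenitor list (0.064).

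Liver was compared next. Several acute phase proteins and enzymes of amino acid and fasting metabolism were lower in KO, and HBZ was higher. The median log2 change of all genes was −0.19, and changes of single liver genes are relative to it. CRP, the C-reactive protein, stood at 2.57 and 0.622 FPKM against 287 and 701 and fell by 7.36 (SE 0.57, limma adjusted p = 0.00031), and ORM1, an acute phase glycoprotein, fell by 7.39 (SE 0.71, adjusted p = 0.00075). SDS, serine dehydratase, fell by 6.5 (SE 0.46, adjusted p = 0.00025), the serum amyloid SAA4 fell by 6.49 (SE 0.8, adjusted p = 0.0038) and AZGP1 fell by 5.53 (SE 0.45, adjusted p = 0.00031). HBZ rose by 6.43 (SE 0.54, adjusted p = 0.00057) and HBB fell by 2.39 (SE 0.39, adjusted p = 0.012). The drug-metabolising CYP2C75 and CYP2C93, whose reads can be shared with close relatives, rose by 5.39 and 4.31 (adjusted p = 0.00057 and 0.015), the immediate early factor EGR1 by 3.96 (adjusted p = 0.0092) and the macrophage chitinase CHIT1 by 3.65 (adjusted p = 0.025).

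Of 21 acute phase genes, 7 fell and 0 rose in KO liver, or 16 and 0 adjusted over the list alone (median −1.95 against −0.19 for all genes, adjusted p = 1e-11, adjusted p = 0.5 with an estimated correlation). Of 34 mature hepatocyte genes, 10 fell and 0 rose, or 21 and 0 adjusted over the list alone (median −1.80, adjusted p = 1e-14, adjusted p = 0.4 with an estimated correlation). The tyrosine aminotransferase TAT was at −3.74 and the glutaminase GLS2 at −2.81. Of 18 gluconeogenesis genes, 5 fell and 0 rose, or 8 and 0 adjusted over the list alone (median −1, adjusted p = 5.2e-08, adjusted p = 0.4 with an estimated correlation). G6PC was at −2.97 and GOT1 at −2.91. Of 25 fatty acid oxidation genes, 3 fell and 0 rose, or 15 and 0 adjusted over the list alone (median −1.19, adjusted p = 1e-09, adjusted p = 0.5 with an estimated correlation), with CPT1A, the gatekeeper of mitochondrial fatty acid import, at −4.02. Of 22 glucocorticoid and fasting genes, 4 fell and 0 rose, or 11 and 0 adjusted over the list alone (median −1.30, adjusted p = 1.9e-05, adjusted p = 0.41 with an estimated correlation). Of 20 macrophage genes, 3 fell and 0 rose, or 16 and 0 adjusted over the list alone (median −2.53, adjusted p = 3.8e-13, adjusted p = 0.51 with an estimated correlation). MARCO and CD163, both scavenger receptors, were at −4.04 and −3.43. Of 21 erythroid genes, HBZ and AHSP rose and HBB fell, or 17 and 1 adjusted over the list alone (median 2.12, adjusted p = 1e-14, adjusted p = 0.5 with an estimated correlation). Of 14 fetal liver genes, 1, DLK1, rose by 2.65 and 0 fell, or 3 and 0 adjusted over the list alone (median 0.68, adjusted p = 0.0013, adjusted p = 0.56 with an estimated correlation). Alpha-fetoprotein, AFP, stood at 142 and 558 FPKM against 79.1 and 71.1 without passing (adjusted p = 0.16). Of 33 cell cycle genes, 0 passed under either adjustment, including adjusted over the list alone, though 32 were positive (median 0.90, adjusted p = 5.5e-10, adjusted p = 0.56 with an estimated correlation). Of 19 immediate early genes, 1, EGR1, rose and 0 fell, or 6 and 0 adjusted over the list alone (median 1.66, 2.36 in KO2 and 0.34 in KO3, adjusted p = 8.8e-10, adjusted p = 0.5 with an estimated correlation). Cell cycle medians were 0.18 in KO2 and 1.61 in KO3, with WT2 0.42 above the WT mean, so KO3 carried this list. Erythroid medians were 1.20 and 2.97, with WT2 0.81 above the WT mean, and fetal liver medians 0.22 and 0.76, with WT2 0.28 above it. Of 22 interferon-stimulated genes, 2 fell, IFI6 and IFI27, and 0 rose, or 9 and 1 adjusted over the list alone (median −0.94, adjusted p = 6.4e-05, adjusted p = 0.56 with an estimated correlation).

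In liver 134 of 12207 genes passed, 32 higher and 102 lower. After quantile normalisation 19 of the 134 still passed, and CYP2C93, EGR1, CHIT1, SAA4, HBB, GOT1 and IFI27 did not. Leaving out KO2 gave 0 genes by limma, which ended each liver call above (smallest adjusted p 0.052), with 1742 at an unadjusted p under 0.05, and leaving out KO3 gave 111, WT2 337 and WT3 151, while the animal number as a block gave 233. Without KO3 CHIT1 (adjusted p = 0.11), SAA4 (0.06), HBB (0.063), GOT1 (0.056), IFI27 (0.11), IFI6 (0.064), AHSP (0.084) and DLK1 (0.058) missed the threshold.

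Heart was compared likewise. NPPA, the atrial natriuretic peptide, was higher in KO and ACTA1, the skeletal alpha-actin that fetal and stressed heart expresses, was lower. NPPA stood at 609 and 1130 FPKM against 63.1 and 103 and rose by 3.35 log2 units (SE 0.39, limma adjusted p = 0.0044). ACTA1 stood at 15.3 and 104 FPKM against 933 and 2150 and fell by 5.09 (SE 0.65, adjusted p = 0.0074). GPX3, a secreted glutathione peroxidase, rose by 3.22 (SE 0.37, adjusted p = 0.0044), the phospholipase PLA2G2A by 3.19 (SE 0.54, adjusted p = 0.037) and the protease inhibitor SERPINA5 by 3.03 (SE 0.43, adjusted p = 0.015).

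HBZ rose by 3.81 in heart (SE 0.5, limma adjusted p = 0.0085), and HBB fell by 3.75 (adjusted p = 0.025). PDK4 (−3.29, adjusted p = 0.037), the sodium channel SCN7A (−3.03, adjusted p = 0.026) and MFAP5, a microfibril protein (−2.96, adjusted p = 0.047), fell as well. Of 18 glucocorticoid and fasting genes, PDK4 and KLF9 fell and 0 rose, or 4 and 0 adjusted over the list alone (median −1.02, adjusted p = 1.2e-08, adjusted p = 0.63 with an estimated correlation). Of 14 atrial genes, 1, NPPA, rose and 0 fell, also adjusted over the list alone (median 0.19, adjusted p = 0.023, adjusted p = 0.63 with an estimated correlation). The atrial light chain MYL7 was at 1.13 (adjusted p = 0.36). Macrophage genes stood lower with the same animals, with 0 of 16 past the threshold over all genes and 7 lower adjusted over the list alone (median −1.08, adjusted p = 6.9e-13, adjusted p = 0.63 with an estimated correlation). Of 23 fibroblast, 15 smooth muscle and 19 interferon genes in heart, 22, 14 and 18 were lower, 0 passed over all genes, and 0, 1 and 3 were lower adjusted over the list alone. Their medians were −0.85, −0.71 and −1.17 (camera adjusted p = 9.8e-08, 5.3e-06 and 1.2e-08, adjusted p = 0.63 with an estimated correlation for each). Of 49 ribosomal protein genes, 0 passed over all genes and 40 rose adjusted over the list alone (median 0.95, adjusted p = 2.5e-37, adjusted p = 0.63 with an estimated correlation). In KO2 and KO3 the medians were −1.78 and −0.33 for the glucocorticoid list, 0.04 and 0.44 for the atrial list and −1.63 and −0.63 for the macrophage list. Heat shock genes stood apart in KO2, with a median of 3.22 over 19 genes against 0.4 in KO3, and 11 were higher adjusted over the list alone (median 1.83, adjusted p = 5.3e-12, adjusted p = 0.63 with an estimated correlation).

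In heart 22 of 12256 genes passed, 13 higher and 9 lower. By limma 0 genes passed after quantile normalisation (1200 at an unadjusted p under 0.05) and 0 with a filter at 5 FPKM (701 at an unadjusted p under 0.05), against 6 at a pseudocount of 0.1 and 226 with the animal number as a block. Leaving out KO3 gave 199 genes, WT2 72, WT3 105 and KO2 30, and NPPA, GPX3, SERPINA5, ACTA1 and HBB passed each time. HBZ (adjusted p = 0.056), PDK4 (0.17), SCN7A (0.053), MFAP5 (0.12), KLF9 (0.14), the heat shock list (0.19) and the atrial list (0.11) missed the threshold without KO2, PLA2G2A (0.075) without KO3, SCN7A (0.091), MFAP5 (0.14) and KLF9 (0.062) without WT2, and KLF9 (0.051) without WT3.

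Brain was compared next. Levels of myelin, astrocyte and inhibitory neuron genes were lower in both KO animals and several muscle transcripts were higher, but 0 genes passed the threshold. The median log2 change of all genes was −0.20, and changes of single brain genes are relative to it. GPR17, a receptor of oligodendrocyte precursors, stood at 1.97 and 0.696 FPKM against 26.2 and 20.6 (−3.24, SE 0.38, limma adjusted p = 0.17). CXCL14, a chemokine, stood at 13.9 and 6.39 against 65.7 and 81.1 (−2.61, SE 0.43, adjusted p = 0.39), and the lipid phosphatase PLPP2 at 0.334 and 0.644 against 5.38 and 8.62 (−2.20, adjusted p = 0.39). CKM, the muscle creatine kinase, stood at 12.1 and 17.9 FPKM against 0.342 and 0.0306 (3.92, SE 0.33, adjusted p = 0.13), and the fast muscle light chains MYLPF and MYL1 at 9.83 and 16.4 against 0.292 and 0.159 (3.67) and 10.1 and 16.2 against 0.35 and 0 (3.77), both with an adjusted p of 0.13.

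All 21 oligodendrocyte and myelin genes were lower in KO brain, with 0 past the threshold over all genes and 5 lower adjusted over the list alone (median −1.78 against −0.20 for all genes, adjusted p = 5.7e-08, adjusted p = 0.76 with an estimated correlation). Their median was −1.37 in KO2 and −1.63 in KO3. Of 18 astrocyte genes, 17 were lower, 0 passed over all genes and 5 were lower adjusted over the list alone (median −1.10, adjusted p = 9.8e-05, adjusted p = 0.76 with an estimated correlation). The glutamate transporter SLC1A2 was at 34.3 and 8.06 FPKM against 203 and 194 (adjusted p = 0.39). Of 18 inhibitory neuron genes, 17 were lower, 0 passed over all genes and 2 were lower adjusted over the list alone (median −1.34, adjusted p = 0.00034, adjusted p = 0.76 with an estimated correlation). The GABA-synthesising enzyme GAD2 was at −1.90. Of 38 synaptic genes, 36 were lower and 0 passed, also adjusted over the list alone (median −0.90, adjusted p = 0.0013, adjusted p = 0.76 with an estimated correlation). Synaptic medians were −1.61 in KO2 but −0.13 in KO3. All 15 microglia genes were lower and 0 passed, also adjusted over the list alone (median −1.60, adjusted p = 0.014, adjusted p = 0.76 with an estimated correlation). Microglia medians were −0.37 in KO2 but −3.49 in KO3, where the complement gene C1QA was at 0.0837 FPKM against 44.7 and 48.3 in WT. Of 11 choroid plexus, ependyma and meninges genes, 10 were higher and 0 passed, also adjusted over the list alone (median 0.95, adjusted p = 0.0012, adjusted p = 0.76 with an estimated correlation). The transthyretin gene TTR was at 110 FPKM in KO2 and 1.77 in KO3 against 0.929 and 0.404. All 49 ribosomal protein genes were higher and 0 passed, also adjusted over the list alone (median 0.90, adjusted p = 1.5e-20, adjusted p = 0.76 with an estimated correlation). In KO2 and KO3 the medians were 1.33 and 0.43 for ribosomal, 1.29 and 0.35 for choroid plexus and −0.54 and −1.96 for astrocyte genes. Other lists moved with KO2, as fibroblast and matrix genes had a median of 1.43 in KO2 and −0.07 in KO3 (adjusted p = 0.0016, adjusted p = 0.76 with an estimated correlation). Heat shock genes had 1.15 and 0.15 (adjusted p = 0.0012, adjusted p = 0.76 with an estimated correlation). The fibroblast list missed the threshold without KO2 (mean −0.17, adjusted p = 0.87), and 0 members of either list passed, also adjusted over the list alone.

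In brain limma called 0 of 13392 genes (1701 at an unadjusted p under 0.05, smallest adjusted p 0.077), against 89 with libraries nested in animals, 635 in 1 fit of all tissues and 4168 with libraries as replicates, which treats repeats as animals. Leaving out KO3 gave 2131 genes, KO2 53, and WT2 or WT3 0 by limma (335 and 442 at an unadjusted p under 0.05), and without KO2 the synaptic list mean went to −0.14, above that of other genes, and without KO3 the microglia list went to −0.20 (adjusted p = 0.89) and the astrocyte list to −0.68 (adjusted p = 0.053). KO2 correlated with KO3 at 0.874 across genes, and KO3 correlated with WT2 and WT3 at 0.922 and 0.933, so the KO animals were farther from each other than KO3 was from WT.

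Lung was compared as well. Surfactant genes of type II pneumocytes were lower in both KO animals, though 0 genes passed the threshold. The median log2 change of all genes was −0.17, and changes of single lung genes are relative to it. The surfactant protein SFTPA2 stood at 33.2 and 36.2 FPKM against 858 and 677 (−4.25, SE 0.42, limma adjusted p = 0.083). LGI3, a secreted protein, stood at 0.422 and 0.471 against 25.5 and 20.7 (−3.88, adjusted p = 0.087), and HBZ at 45.6 and 27 against 1.27 and 1.52 (4.10, adjusted p = 0.1). CXCL1, a neutrophil chemokine, stood at 33.6 and 25.4 against 2.55 and 0.682 (3.93, adjusted p = 0.17), with repeat libraries of WT2 at 4.02 and 1.07. PIGY stood at 37.4 and 29.1 against 0.196 and 0.135 (5.05, adjusted p = 0.083) and PYURF, which shares its transcript with PIGY, at 0.131 and 1.23 against 53.1 and 33.1 (−4.70, adjusted p = 0.087), so how reads were divided between the pair is uncertain.

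Of 16 surfactant and type II genes, 15 were lower in KO lung, 0 passed over all genes and 10 were lower adjusted over the list alone (median −2.66 against −0.17 for all genes, adjusted p = 1.5e-14, adjusted p = 0.36 with an estimated correlation). Medians were −2.66 in KO2 and −2.02 in KO3. The lysosomal protein LAMP3 was at −4.01 (adjusted p = 0.1), the phosphate transporter SLC34A2 at −3.52 (adjusted p = 0.1) and the collectin SFTPD at −2.77 (adjusted p = 0.19). Of 14 type I pneumocyte genes, 0 passed, also adjusted over the list alone (median −0.83, adjusted p = 0.013, adjusted p = 0.73 with an estimated correlation). Of 18 erythroid genes, 0 passed over all genes and 5 were higher adjusted over the list alone (median 0.89, adjusted p = 1.2e-10, adjusted p = 0.73 with an estimated correlation). Erythroid medians were 0.41 in KO2 and 1.51 in KO3. In lung limma called 0 of 13243 genes (963 at an unadjusted p under 0.05), against 2 after quantile normalisation, SFTPA2 and PIGY at an adjusted p of 0.049 each, 21 with the animal number as a block, 57 with libraries nested in animals, 256 in 1 fit of all tissues and 2170 with libraries as replicates. Leaving out KO2 gave 155 genes, KO3 226, and WT2 or WT3 0 by limma (406 and 465 at an unadjusted p under 0.05), and the type I list missed the threshold without KO2 (adjusted p = 0.13) or WT2 (0.054). KO2 and KO3 correlated at 0.825 across genes in lung, below each KO and WT pair (0.851 to 0.869). Macrophage genes had medians of −1.70 in KO2 and 0.97 in KO3, and heat shock genes 1.23 and −0.67, with neither list past the threshold (camera adjusted p = 0.21 and 0.13). Glycolysis (median 0.66, −0.09 in KO2 and 1.41 in KO3) and hypoxia genes (0.43, −0.52 and 1.40) were called (camera adjusted p = 2.1e-06 and 0.0047, adjusted p = 0.73 and 0.81 with an estimated correlation), but without KO3 had means of −0.07 and −0.37. T cell (−0.93) and neutrophil genes (−0.62) stood lower (camera adjusted p = 0.02 and 0.021, adjusted p = 0.78 and 0.73 with an estimated correlation). They missed the threshold without KO3 (0.38) or WT3 (0.092) and without KO2 (0.3) or WT2 (0.56), as hypoxia genes did without WT3 (0.071). No member of these 4 lists passed over all genes, and adjusted over the list alone 1 hypoxia gene was higher and 1 T cell gene lower.

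Thymus asked whether T cell precursors and their stroma differed. Cortical thymocyte genes were lower in KO2 and near WT in KO3, and no named gene passed. The median log2 change of all genes was −0.21, and changes of single thymus genes are relative to it. RAG1, the recombinase of T cell receptor assembly, stood at 21 and 241 FPKM against 325 and 343 (−1.99, SE 0.96, limma adjusted p = 0.7), and the coreceptor CD8B at 63 and 385 against 470 and 479 (−1.39, adjusted p = 0.7). The epithelial keratins KRT14 and KRT5 stood at 239 and 90.4 against 15.7 and 28.7 (2.94, adjusted p = 0.69) and at 198 and 93.6 against 28 and 29.7 (2.40, adjusted p = 0.69). VEGFA stood at 75.5 and 50.2 against 6.49 and 4.4 (3.51, adjusted p = 0.23), HBZ at 23.6 and 57.6 against 0.385 and 0.564 (4.91, adjusted p = 0.091) and HBB at 142 and 66.7 against 1410 and 1250 (−3.55, adjusted p = 0.15). UCP1, the uncoupling protein of brown fat, stood at 0.0645 and 0.0261 against 29 and 9.28 (−3.86, adjusted p = 0.22), the signalling peptide ASIP at 1.07 and 1.77 against 20.7 and 12.6 (−2.65, adjusted p = 0.29), and ACTA1 at 5.63 and 19.3 against 0.572 and 0.269 (3.25, adjusted p = 0.52).

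Of 23 cortical thymocyte genes, 21 were lower in KO and 0 passed, also adjusted over the list alone (median −1.01 against −0.21 for all genes, adjusted p = 0.00097, adjusted p = 0.68 with an estimated correlation). Medians were −1.76 in KO2 and −0.25 in KO3. Of 21 thymic epithelium genes, 15 were higher, 0 passed over all genes and 2 were higher adjusted over the list alone (median 0.70, adjusted p = 3.1e-05, adjusted p = 0.51 with an estimated correlation). Fibroblast and matrix genes stood higher beside them, with a median of 0.75 over 21 genes, 0.86 in KO2 and 0.49 in KO3 (adjusted p = 3.1e-08, adjusted p = 0.51 with an estimated correlation). Heat shock genes did too, with 0.80 over 20 genes, 1.20 in KO2 and 0.35 in KO3 (adjusted p = 3.7e-08, adjusted p = 0.51 with an estimated correlation), and 0 members of either list passed, also adjusted over the list alone. The thymic protease PRSS16 stood lower, at 115 and 151 FPKM against 522 and 288. Of 11 adipocyte genes, 0 passed over all genes and 5 were lower adjusted over the list alone (median −1.35, adjusted p = 5.5e-06, adjusted p = 0.51 with an estimated correlation). Of 16 imprinted genes, 0 passed over all genes and 3 were higher adjusted over the list alone (median 0.68, adjusted p = 3.4e-08, adjusted p = 0.51 with an estimated correlation). Fry called this list (adjusted p = 0.045). In thymus limma called 1 of 12961 genes, LOC102144665, at −5.40 (SE 0.38, adjusted p = 0.0081, without subtracting the median), named after its values were seen. It rested on 1 of the 2 repeat libraries of each WT animal, at 0 and 1924 FPKM in WT2 and 0 and 1650 in WT3, with 0 in each KO thymus library, so the call is not a reliable difference. The cortical thymocyte list missed the threshold without KO2 (mean −0.07, adjusted p = 0.25). Leaving out KO2 gave 12 genes, KO3 533, WT2 20 and WT3 45, and KO3 correlated with WT2 and WT3 at 0.928 and 0.955 against 0.872 with KO2.

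Whether the KO change differed between tissues was tested on each animal's difference between a tissue and the mean of its other 6. MYH3 in muscle exceeded the other tissues by 5.29 log2 units, and UCP3 and MYH1 differed by −6.34 and −4.84. CRP in liver differed by −7.28, ACTA1 in heart by −5.93 and CYP27B1 in kidney by −4.75. This test called 543 genes in kidney, 81 in heart, 44 in liver and 9 in muscle. It called 1 gene each in brain (LOC107126717, 4.71, SE 0.38, limma adjusted p = 0.047), thymus (LOC102144665, the gene above) and lung (PIGY, 5.25, SE 0.39, adjusted p = 0.018), the first of which was named after its value was seen. After quantile normalisation limma gave 350 in kidney, 3 in heart, and 0 in muscle and brain (1355 and 1095 at an unadjusted p under 0.05). A pseudocount of 0.1 gave 59 in kidney, 5 in heart, 59 in liver and 1 in muscle. Ranges without each animal are given below.

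Fetal muscle was compared between month 4 and month 2. Fast myosins and fat-storage genes rose and embryonic sarcomere genes fell. The median log2 change of all genes was 0.16, and changes of single fetal muscle genes are relative to it, with n = 2 libraries per month. MYH1 stood at 516 and 1080 FPKM at month 4 against 0.187 and 0.196 at month 2 and rose by 9.13 (SE 0.29, limma adjusted p = 9.4e-08). MYH2, another fast myosin, rose by 7.38 (SE 0.22, adjusted p = 5.7e-08) and MYH4 by 6.22 (SE 0.85, adjusted p = 0.00049). MYL4, the embryonic light chain, stood at 3.23 and 1.96 FPKM against 324 and 272 and fell by 6.56 (SE 0.21, adjusted p = 1.2e-07), and TNNT2, the cardiac troponin T of embryonic muscle, fell by 6.08 (SE 0.17, adjusted p = 5.7e-08).

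MYBPC2, a fast myosin-binding protein, NRAP, a protein of myofibril assembly, the fatty acid desaturase SCD, the triglyceride enzyme DGAT2 and elastin, ELN, rose by 5.77, 5.34, 4.74, 4.21 and 4.09 in fetal muscle, with limma adjusted p values of 8.6e-06, 1.4e-07, 1.7e-06, 4.4e-06 and 0.0075. CPLX1, MYL5, MYBPH and the liver-type plasma proteins APOA2, ALB and TTR fell, at −4.67, −4.6, −4.32, −4.28, −3.81 and −3.29, with adjusted p values of 1.7e-06, 3.2e-06, 3.2e-06, 1e-05, 0.00089 and 0.00045. SIRT6 fell by 0.87 (SE 0.21, adjusted p = 0.027) but missed the threshold without either month 2 library (adjusted p = 0.075 and 0.39). Of 32 fast-twitch genes, 25 rose and 0 fell, also adjusted over the list alone (median 1.44, adjusted p = 1.6e-08, adjusted p = 0.59 with an estimated correlation). Of 23 fetal and regenerating muscle genes, 14 fell and 0 rose, or 15 and 0 adjusted over the list alone (median −1.09, adjusted p = 6.5e-10, adjusted p = 0.29 with an estimated correlation). Of 12 adipocyte genes, all 12 rose, also adjusted over the list alone (median 1.95, adjusted p = 7.3e-08, adjusted p = 0.46 with an estimated correlation). The lipoprotein lipase LPL was at 3.29. Of 49 ribosomal protein genes, 46 fell and 1, RPL37, rose, also adjusted over the list alone (median −1.48, adjusted p = 6.3e-24, adjusted p = 0.29 with an estimated correlation). In fetal muscle 4687 of 12352 genes passed, 2753 higher and 1934 lower. After quantile normalisation 4466 passed and the share higher went from 58.7% to 46.8%, and leaving out the month 2 libraries in turn gave 1648 and 1455 genes, against 4578 and 6713 for those of month 4.

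Fetal brain was compared between month 4 and month 2. NRGN, AQP4 and P2RY12, genes of neurons, astrocytes and microglia, rose, and NEUROG2, a gene of new neurons, fell. NRGN, a postsynaptic calmodulin-binding protein, stood at 945 and 1330 FPKM at month 4 against 58.6 and 195 at month 2 and rose by 3.37 log2 units (SE 0.5, limma adjusted p = 0.009, n = 2 libraries per month). AQP4, the water channel of astrocytes, rose by 3.11 (SE 0.22, adjusted p = 0.00045) and P2RY12, a microglial receptor, by 1.99 (SE 0.24, adjusted p = 0.0038). NEUROG2, a transcription factor that starts neuron formation, fell by 2.55 (SE 0.29, adjusted p = 0.0029). The metallothionein MT3, the zinc transporter SLC30A3, angiotensinogen, AGT, and the glial receptor GPR37L1 rose by 3.79, 3.57, 3.31 and 3.18, the ribosomal protein genes RPL37 and RPL39 by 4.31 and 3.69, and PTH2 was at 10.9 and 13.7 FPKM where month 2 was listed at 0. MFAP2, ADAMTS7, CHRDL1, HBZ, GPC2, TMSB15A and EPHA3 fell, at −2.12, −2, −1.89, −1.85, −1.84, −1.8 and −1.71, with adjusted p values up to 0.035.

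Of 18 astrocyte genes, 8 rose and 0 fell in fetal brain, or 13 and 0 adjusted over the list alone (median 1.17, adjusted p = 7.6e-11, adjusted p = 0.39 with an estimated correlation). Of 38 synaptic genes, 8 rose and 0 fell, or 19 and 0 adjusted over the list alone (median 0.74, adjusted p = 1.7e-09, adjusted p = 0.63 with an estimated correlation). Of 14 oligodendrocyte genes, 3 rose and 0 fell, or 10 and 0 adjusted over the list alone (median 1.01, adjusted p = 1.7e-07, adjusted p = 0.42 with an estimated correlation). Of 11 microglia genes, 9 rose and 0 fell, also adjusted over the list alone (median 1.50, adjusted p = 2.5e-08, adjusted p = 0.48 with an estimated correlation). Of 25 immature neuron genes, 1, IGFBPL1, fell and 0 rose, or 9 and 0 adjusted over the list alone (median −0.36, adjusted p = 6.4e-05, adjusted p = 0.39 with an estimated correlation). With no level filter limma called 0 genes in fetal brain (3265 at an unadjusted p under 0.05). In fetal brain 526 of 13114 genes passed, 430 higher and 96 lower. After quantile normalisation 234 passed, 225 of them among the 526, without ADAMTS7 and GPC2, and leaving out either month 4 library gave 0 genes by limma (2019 and 1569 at an unadjusted p under 0.05), against 786 and 1369 for the month 2 libraries.

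Whether KO newborn tissue lay nearer the earlier fetal stage was asked by following the fetal stage genes in the newborn comparison of the same tissue. In KO muscle the 383 tested month 2 genes had a mean log2 change of 0.476 and the 484 month 4 genes one of −0.58, against −0.038 and 0.001 for all other genes (camera adjusted p = 3.1e-11 and 2.9e-14, adjusted p = 0.16 and 0.32 with an estimated correlation). Of the month 2 genes 20 rose and 8 fell in KO muscle, and of the month 4 genes 6 rose and 53 fell. Leaving out KO2 brought the mean of the month 4 genes to −0.171, with 12 lower, and leaving out KO3 brought it to −0.989, with 55 lower. Without WT2 or WT3, 27 and 29 month 4 genes were lower and 12 and 10 month 2 genes were higher. In KO brain the 73 month 2 genes were at 0.176 and the 388 month 4 genes at −0.729, against −0.185 and −0.167 for other genes (camera adjusted p = 0.00049 and 2.1e-06, adjusted p = 0.32 and 0.16 with an estimated correlation), with 0 members called in either set by limma. Lists of early genes were not called in KO brain. KO2 and KO3 medians were 0.24 and −0.97 (radial glia) and −0.75 and 0.11 (immature neurons). Brain month 2 means were −0.051 without KO2, 0.404 without KO3, 0.267 without WT2 and 0.086 without WT3, and the month 4 mean −0.681 without KO2. The score of an animal, the mean of month 4 genes minus that of month 2 genes, was −0.71 and 0.21 in KO muscle against 0.74 and 0.88 in WT, and 0.71 and 1.27 in KO brain against 1.69 and 2.10 in WT. In both tissues each KO animal scored below each WT animal, and the exact permutation test gave p = 0.33, the smallest it can give.

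The sets of the other tissue gave differences of the same sign with all 4 animals. The muscle sets had means of 0.51 and −0.438 in KO brain (camera adjusted p = 1.8e-23 and 0.00049, adjusted p = 0.16 and 0.13 with an estimated correlation), and the brain sets had 0.372 and −0.177 in KO muscle (camera adjusted p = 0.0012 and 0.077, adjusted p = 0.16 and 0.63 with an estimated correlation). In KO muscle the brain month 4 genes had a mean of 0.027 without KO2 (other genes 0.206) and −0.049 without WT2 (other genes −0.048, camera adjusted p = 0.87), and the brain month 2 genes missed the threshold without KO2 (adjusted p = 0.069). In KO brain without KO2 muscle and brain month 2 genes were at 0.303 and −0.051, above other genes. Ribosomal genes, lower at month 4 in muscle, higher in KO brain, were not set apart.

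**Figure D2:**
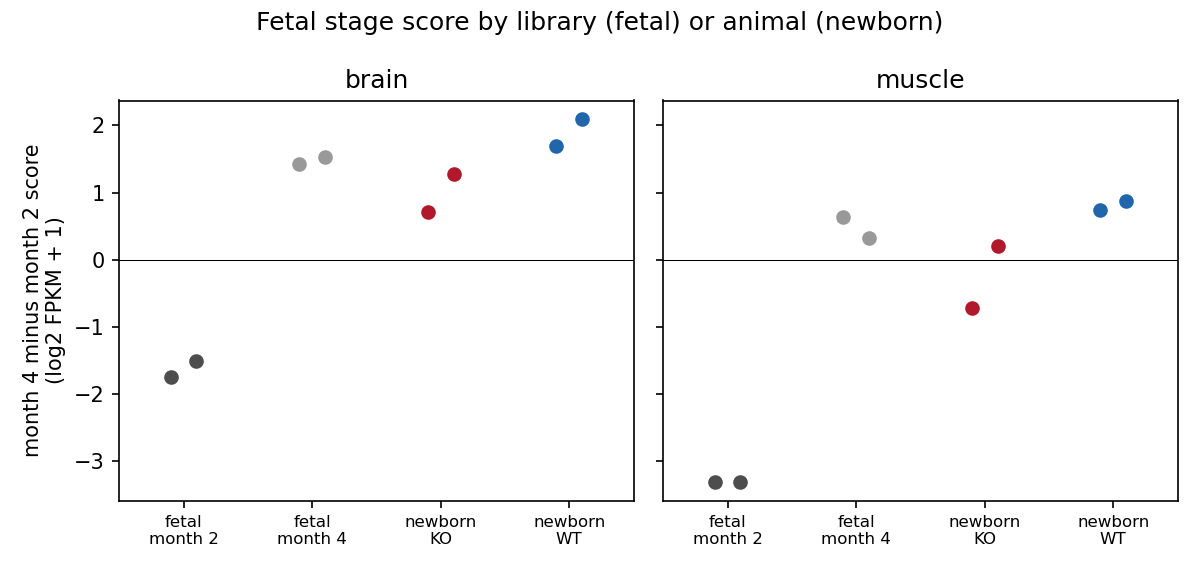
Fetal stage score on the vertical axis (mean log2(FPKM + 1) of month 4 genes minus that of month 2 genes) for brain and muscle, with 1 point per fetal library or per newborn animal. KO animals lie below WT animals in brain (0.71 and 1.27 against 1.69 and 2.10) and in muscle (−0.71 and 0.21 against 0.74 and 0.88), and fetal and newborn values come from tables that may have been normalised separately.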

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

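The tests on HBZ and HBB and on the fetal stage genes, and their predictions, were chosen only after the results were seen, while the predictions on muscle transcripts in KO brain were written before.

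Muscle transcripts stood higher in the brain of KO2 and KO3. Their median was 5.08 and 2.88 FPKM against 0.399 and 0.159 in WT. It covers 19, 23, 26 and 27 fast-twitch genes abundant in the same animal's muscle. Reads of muscle libraries misassigned evenly would show in all tissues alike, but the median in brain was 26.9 times that in liver in KO2 and 11.2 times in KO3, which argues against even misassignment. In KO3 the median was 2.63 FPKM in thymus and 0.897 in lung, so misassignment to some libraries stays open. Muscle tissue or RNA in the brain samples would give one common share of the muscle level, with a correlation across genes above 0.7 in both animals, and it was 0.58 in KO2 and 0.65 in KO3, against −0.13 and −0.01 in WT. The median share was 0.27% and 0.26% (highest 15% and 16%, in WT 17% and 14%). The correlation lay between the predicted value and the excluding one, so muscle RNA stays open, and a change in brain was not tested.

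HBZ stood higher and HBB lower in KO tissues. More blood of the WT kind would raise both globins, but HBB, part of the pattern as first seen, was lower past the threshold in 4 tissues, which argues against it and not against more blood of another globin make-up. A state of KO2 alone would leave KO3 within the WT range, but HBZ in KO3 lay above both WT animals in 7 tissues. HBZ was chosen for its calls in 4 tissues, and thymus, lung and brain (near the floor) of the same animals are no separate test. Red cells of an earlier type in both KO animals stay open. So does any difference from the WT animals other than genotype, such as gestational age at birth, which is not given. Reads shared between globin genes were not tested.

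Month 2 genes stood higher and month 4 genes lower in KO muscle and brain. All 4 sets kept their direction against other genes without KO2, but KO3 is 1 animal and KO2 alone stays open. After quantile normalisation all 4 still passed at the fixed inter-gene correlation, which argues against scaling alone. With an estimated correlation all 4 missed the threshold before either change (adjusted p = 0.32 and 0.16 in brain, 0.16 and 0.32 in muscle), and the mean of brain month 2 genes was −0.051 without KO2. The sets of the other tissue moved 1.06 times as far as brain's own sets in brain and 0.51 times in muscle, at the bound of 0.5. Leaving out each animal gave ratios of 0.82 to 1.41 in brain and 0.4 to 0.72 in muscle. A delay common to tissues may also move both sets, so the ratios cannot separate it from a general difference of KO2 and KO3. Whether genotype or another difference between the animal pairs lies behind the pattern was not tested.

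A library far from the other 3 was found in 8 of 288 groups of 4 libraries, where chance gives about 1 in 20 for independent values. These groups are 2 repeat libraries of each of 2 animals, so that rate need not hold for them. The gap over the range was 1 for HBZ and 0.86 for PEG10 in WT muscle, 0.91 for MYLPF in KO brain, 0.91 for HBZ and 0.91 for SIRT6 in WT brain, 0.95 for PYURF in KO lung, 0.86 for IFI27 in KO kidney and 0.89 for CRP in WT kidney.

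By the test of the difference, the KO change differed from that in other tissues, where some are hardly expressed, for these genes. In muscle the difference was 5.29 for MYH3, 3.19 for PEG10, 3.37 for RTL1, −6.34 for UCP3, −5.2 for CHAC1, −4.84 for MYH1 and −4.16 for PFKFB3. In liver it was 5.2 for CYP2C75, 3.77 for EGR1, −7.59 for ORM1, −7.28 for CRP, −6.17 for SDS, −6.68 for SAA4 and −5.29 for AZGP1. Heart differed by 3.01 for NPPA, 3.76 for GPX3, 3.53 for PLA2G2A, 3.65 for SERPINA5, −5.93 for ACTA1, −2.63 for SCN7A, −2.48 for MFAP5 and −2.09 for IFI27, and lung by 5.25 for PIGY. Kidney differed by 3.52 for LYPD1, 2.89 for SHISA3, 1.6 for SAMD11, 1.93 for B4GALNT4, −4.45 for HMOX1, −4.75 for CYP27B1, −4.18 for MIOX and −3.84 for G6PC.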

How the results depend on the processing

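The crossed block in fetal brain, the alternatives of the tissue differences, leaving out fetal libraries for the lists and the comparison of repeat libraries were chosen only after the results were seen. The cause was not tested for the changes below, except that fewer animals were used where 1 was left out and that libraries as replicates count repeats as animals. Where 1 animal was left alone in a group, it was assumed to vary like the other group. The fits named above that used the variance trend alone do not test a gene against its own spread. Of the results for named genes, 274 kept their direction and side of the threshold after quantile normalisation and 96 became weaker. With a pseudocount of 0.1, 365 kept them and 11 became weaker, at 5 FPKM 322 and 19, and with no level filter 188 and 170. Leaving out an animal or library kept 1094 and weakened 281, and for the called lists kept 480 and weakened 89. Quantile normalisation kept 132 list calls and weakened 13, fry kept 11 and weakened 135, and an estimated correlation weakened 146. Read depth is unknown and no limit from it could be set. Repeat libraries lay over 1 log2 unit apart in 5 of 281 called genes in muscle, 1 of 1 in thymus, 2 of 134 in liver, 1 of 22 in heart and 7 of 806 in kidney.

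Genes called with libraries as replicates were 4168 in brain, 2768 in muscle, 1484 in thymus, 3545 in liver, 1539 in heart, 2170 in lung and 5119 in kidney. With libraries nested in animals they were 89 in brain, 9 in thymus, 430 in liver, 57 in lung and 1566 in kidney. In 1 fit of all tissues they were 635 in brain, 81 in thymus, 891 in liver, 103 in heart, 256 in lung and 996 in fetal brain. With no level filter limma called 0 in muscle, 0 in thymus, 0 in liver, 0 in heart, 0 in kidney and 0 in fetal brain (2229, 1130, 2198, 1631, 3656 and 3265 at an unadjusted p under 0.05), and 2488 in fetal muscle. At 5 FPKM it called 180 in muscle, 3 in thymus, 0 in heart (701 at an unadjusted p under 0.05) and 3012 in fetal muscle. Quantile normalisation gave 14 in muscle, 19 in liver, 0 in heart (1200 at an unadjusted p under 0.05), 2 in lung, 234 in fetal brain and 7 in the average over tissues. For tissue differences it gave 0 in brain and 0 in muscle (1095 and 1355 at an unadjusted p under 0.05), 3 in heart and 350 in kidney. A pseudocount of 0.1 gave 0 in thymus (750 at an unadjusted p under 0.05) and 6 in heart, and for tissue differences 0 in brain (995), 1 in muscle, 5 in heart and 59 in kidney.

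The animal number as a block gave 0 in thymus by limma (1079 at an unadjusted p under 0.05), 233 in liver, 226 in heart and 21 in lung, and a block crossed over the months gave 1101 in fetal brain, while the block moved no other count by over 1.5 times. The correlation of deviations from the group mean between animals of the same number was 0 in brain, 0.03 in muscle, 0.09 in thymus, −0.1 in liver, −0.01 in heart, −0.02 in lung, −0.03 in kidney, −0.23 in fetal brain, 0.08 in fetal muscle and −0.05 in the average. Of the 3 ways to split 4 animals, no share under 0.05 is possible, and the highest count in another split was 3 in muscle against 281, 2 in thymus against 1, 1 in heart against 22 and 0 in kidney against 806.

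With an estimated correlation the fetal stage sets kept their means, 0.176 and −0.729 in brain and 0.476 and −0.58 in muscle, but missed the threshold, and the lists called in newborn tissues went from 102 to 0, and to 4 with fry.

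Leaving out each animal or library gave 0 to 2131 genes in brain, 97 to 279 in muscle, 12 to 533 in thymus, 0 to 337 in liver, 30 to 199 in heart, 0 to 226 in lung, 172 to 1508 in kidney, 0 to 1369 in fetal brain, 1455 to 6713 in fetal muscle and 49 to 1100 in the average. For tissue differences it gave 16 to 1576 in brain, 75 to 207 in muscle, 3 to 616 in thymus, 0 to 91 in liver, 10 to 695 in heart, 0 to 65 in lung and 199 to 1463 in kidney.

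Directions that turned after quantile normalisation were those of ribosomal proteins in thymus (−0.1), SIRT6 in brain (0.04), IGF2 in heart (0) and in fetal muscle (0.68), and PDK4 in brain (0.13) and liver (0.03). Directions that turned in at least 1 fit without an animal or library had these ranges of list means. In brain they were −0.25 to 1.14 for NF-kB targets, −0.33 to 1.06 for immediate early genes, −0.3 to 0.82 for smooth muscle genes, and, against other genes, −1.72 to −0.14 for synaptic genes and −3.13 to −0.2 for microglia genes. Elsewhere they were −0.27 to 1.17 for heat shock and −2.14 to 0.42 for adipocyte genes in muscle, −0.85 to 0 for immediate early genes in heart, −0.19 to 0.39 for ribosomal and −0.37 to 1.33 for hypoxia genes in lung, −0.36 to 0.88 for cell cycle genes in kidney and 0.3 to 0.64, against other genes, for oxidative phosphorylation in fetal muscle. In the average they were −0.17 to 0.4 for cell cycle, −0.26 to 0.78 for glycolysis and −0.12 to 1.85 for heat shock. For genes they were −0.63 to 0.09 for SIRT6 in muscle, −0.08 to 0.49 in lung, −0.98 to 0.06 in kidney and −0.51 to 0.36 in fetal brain, and −0.65 to 1.76 for IGF2 in fetal brain. HBB in lung ran from −3.27 to 0.04, PDK4 from −0.87 to 0.76 in brain and −0.71 to 0.09 in liver, IFI27 from −0.21 to 2.01 in brain, −0.59 to 1 in thymus and −1.89 to 0.27 in lung, and BMP10 in heart from −0.02 to 2.68.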

Other observations

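Which lists of the thymus are described here, and the reading of muscle transcripts in the thymus of KO3, were chosen only after the results were seen.

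Other gene groups stood apart from the remaining genes in KO thymus by camera. Glycolysis genes had a median of 0.79 over 24 genes (adjusted p = 3.1e-08, adjusted p = 0.56 with an estimated correlation), and neutrophil genes one of 0.99 over 17 genes (adjusted p = 3.4e-08, adjusted p = 0.51 with an estimated correlation). Cell cycle genes had a median of −0.73 over 35 genes (adjusted p = 0.00023, adjusted p = 0.67 with an estimated correlation). Each was carried mainly by 1 KO animal, with medians in KO2 and KO3 of 0.13 and 1.39 for glycolysis, 0.21 and 1.87 for neutrophil and −1.15 and −0.21 for cell cycle genes. Without KO3 the means of glycolysis and neutrophil genes were 0.1 and 0.13, and without KO2 that of cell cycle genes was −0.22. No member of these lists passed limma's threshold over all genes, where 767 genes had an unadjusted p under 0.05.

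Transcripts of skeletal muscle were also found in the thymus of KO3. Its fast-twitch genes had a median of 2.63 FPKM there, 0.41% of the level in the muscle of the same animal, and correlated with it at 0.92 across genes.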
